A study of Homo sapiens with 16 samples.

How the data were processed

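RNA was measured in the human osteosarcoma line 143B, either wild type (WT) or expressing ScURA. ScURA is the dihydroorotate dehydrogenase of budding yeast, a cytosolic enzyme that does not pass electrons to the mitochondrial respiratory chain, unlike the human enzyme DHODH. Cells of each genotype received antimycin A and myxothiazol, inhibitors of respiratory complex III, at 20 µM each for 3 days, or the ethanol vehicle. The 4 groups held 4 libraries each, 16 in total, and were taken from the genotype and treatment given with each sample. The medium contained high glucose and dialysed serum. Poly(A) RNA libraries were made with an Illumina TruSeq kit, per the labels' protocols. Whether the kit or the counting kept strand is not given in the sources used here. Reads of a gene and of an antisense gene thus cannot be told apart where their exons overlap.

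The authors deposited estimated counts per gene, which need not be whole numbers, for 60664 genes, of which 35880 had a count above 0 in at least 1 library. The file is a merged table of Salmon gene estimates per its name. The authors also deposited a table of normalized counts, a signal that is never negative, for 16267 genes by symbol. Its values relate to the estimated counts by factors that differ between genes within a library, and the filter that selected its genes is not given in the sources used here. Trim Galore, STAR, Salmon, featureCounts and DESeq2, with the genome build GRCh38, are named in the submitters' processing notes, without versions or order. No column belonged to a sample outside the series. The yeast transgene is not a gene of the human annotation and its expression was not analysed here.

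Estimated counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered by group with filterByExpr, which kept 17980 genes, and libraries were scaled by the trimmed mean of M values (TMM). A quasi-likelihood model with 1 coefficient per group and no other covariate was fitted to all 16 libraries, which left 12 residual degrees of freedom. The contrasts tested were inhibitor against vehicle in each genotype, the difference between those responses (ScURA minus WT), and ScURA against WT under vehicle and under inhibitor. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. A further count required an absolute log2 fold change of at least 1. Levels are CPM, counts scaled to a common library total, after TMM scaling, and are given as mean ± SD of 4 libraries, and log2 fold changes are given ± standard error (SE). Gene positions and types came from GENCODE 29 on GRCh38, matched by Ensembl identifier, which covered 98.6% of the genes tested. Genes are said to overlap where their whole spans do, which does not show that their exons overlap.

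Before the data were examined, 34 gene lists were fixed, with the contrasts, the tests and the rule for named genes. The lists covered nucleotide synthesis, respiratory complexes, mitochondrial and cytosolic translation, stress responses, central metabolism, cell cycle, inflammation, matrix and lineage genes, and markers of epithelial, endothelial, neural and leukocyte cells as a check for other cell types. Each list was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, with adjustment over 170 tests. Camera with the correlation estimated for each list, and fry, which asks whether the genes of a list move one way on balance without a comparison with other genes, were run beside it. For each contrast the named genes were the 6 highest and the 6 lowest fold changes among called genes with a mean log2 CPM of at least 2 and with the 4 values of one group all above the 4 of the other. For the difference between responses this separation was required in at least one genotype. Up to 4 members of each list with the lowest adjusted p were eligible, and DHODH, CAD and UMPS, the enzymes of de novo UMP synthesis, were reported in every contrast. Identifiers without a gene symbol and clone-based names were left out, and some genes that the rule takes are not reported here. Any gene named outside this rule is said to have been chosen after its values were seen.

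Library totals ran from 13409005 to 35532515 estimated counts. No pair of libraries of a group differed as little as counting noise alone would give, the lowest chi-square per degree of freedom being 3.02. Each library was counted as 1 replicate, although this spread may come from library preparation alone. The common biological coefficient of variation was 0.086. On counts simulated from these libraries with 50 genes changed at each of 4 fold sizes, the test of inhibitor against vehicle in WT cells recovered 18%, 60%, 74% and 88% of genes changed 1.25-, 1.5-, 2- and 4-fold. For ScURA against WT cells under vehicle the shares were 34%, 52%, 70% and 96%, and for the difference between responses 14%, 48%, 66% and 82%. Unchanged genes made up 6.25%, 5.97% and 5.41% of the calls. Few genes changed in these simulations, whereas the real comparison in WT cells called 76.9% of genes, so these shares need not hold for it. A list raised by 0.5 on the log2 scale in such counts was called, and 0 of the other lists were. Genes were drawn independently there, whereas the estimated correlation in these libraries reached 0.786 for ribosomal proteins. The simulation therefore does not show how often lists of correlated genes are called wrongly.

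Measures of single libraries were compared by exact two-sided permutation tests, whose smallest possible p with 4 against 4 libraries is 0.0286. Alternatives were DESeq2 size factors, no filter, a stricter filter, DESeq2 1.42.0, limma-voom, limma on log2(value + 1) of the normalized counts deposited by the authors, only the groups compared, the replicate number as a block, mitochondrial genes left out, and each library left out in turn. Scaling by library totals alone, and list tests without mitochondrial genes, were added after seeing the data. The size of both responses was compared among genes called for their mean, a choice that favours neither genotype.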

Results

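RNA from 16 libraries of the human osteosarcoma line 143B was compared in 4 groups of 4, namely WT and ScURA cells, each grown for 3 days with vehicle or with antimycin A and myxothiazol at 20 µM each. The inhibitors block respiratory complex III, and ScURA is a yeast enzyme that makes orotate, a pyrimidine precursor, in the cytosol. The series asks what a cytosolic route of pyrimidine synthesis, independent of mitochondrial electron transport, changes in cells whose respiratory chain is blocked. Library totals ran from 21481656 to 25767706 estimated counts in WT vehicle, 23237525 to 26048933 in WT inhibitor, 13409005 to 21525628 in ScURA vehicle and 16397041 to 35532515 in ScURA inhibitor libraries. Nothing in the labels states that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Adjusted p-values of genes are from edgeR's quasi-likelihood test, those of gene lists from camera, and all fold changes are on the log2 scale.

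Inhibitor-treated WT libraries stood farthest from the others. The first principal component of log2 CPM held 56.8% of the variance and set them apart, the next held 18.8% and set apart the inhibitor-treated ScURA libraries, and both vehicle groups lay close to each other. Cytosolic ribosomal protein mRNAs made up 6.48% ± 0.325 of the counts in WT vehicle and 3.05% ± 0.234 in WT inhibitor libraries, against 6.18% ± 0.214 and 7.83% ± 0.272 in ScURA cells (SD, n = 4 each). The number of genes with at least 10 counts was 15764 ± 243 and 17911 ± 154 in WT cells and 15025 ± 416 and 16400 ± 927 in ScURA cells. This number follows depth as well: it was 15379 in the ScURA inhibitor library with 16397041 counts and 17474 in that with 35532515. The share of noncoding RNAs was 1.17% ± 0.0233 and 2.15% ± 0.0991 in WT cells and 1.12% ± 0.0323 and 1.40% ± 0.0247 in ScURA cells. Vehicle and inhibitor libraries did not overlap in any of these measures in either genotype, which gave the smallest possible value of the exact two-sided permutation test, p = 0.0286 (0.0527 after adjustment over 24 comparisons).

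**Figure D1:**
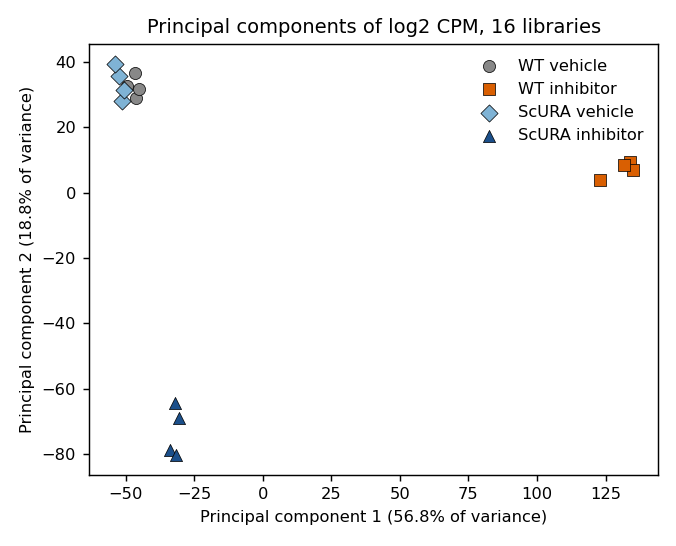
Each point is 1 of the 16 libraries, placed by the first principal component (horizontal axis, 56.8% of the variance) and the next (vertical axis, 18.8%) of log2 CPM, with marker and colour by group. The 4 WT inhibitor libraries lie alone at the right, the 4 ScURA inhibitor libraries alone at the bottom, and the 8 vehicle libraries together.

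In WT cells, complex III inhibition was accompanied by lower mRNA levels across the cytosolic translation machinery and higher levels of ATF4 targets, hypoxia targets and interferon-stimulated genes. These list calls did not hold with an estimated correlation (adjusted p between 0.238 and 0.390). All 74 cytosolic ribosomal protein mRNAs fell, by a median of −1.38, with RPL23 at −2.55 ± 0.0661 and RPL4 at −2.24 ± 0.0556. EEF1A1, the elongation factor that brings aminoacyl-tRNA to the ribosome, went from 12150 ± 575 to 1730 ± 221 CPM (n = 4 each), a change of −2.81 ± 0.0705 (adjusted p = 4.96e-18). It was named after its values were seen. DDIT3, which encodes the stress transcription factor CHOP, rose from 5.06 ± 0.724 to 90.0 ± 6.49 CPM (4.16 ± 0.131, adjusted p = 1.1e-16). Of 17980 genes tested, 7109 were higher and 6709 lower with inhibitor, 76.9% in all, and 4036 and 2318 of them changed at least 2-fold. Higher genes were 51.4% of the calls with TMM scaling and 69.9% (9856 higher, 4235 lower) with library totals alone, a scaling added after seeing the data that moved the median of all genes by 0.345.

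The genes that rose most in WT cells started near the floor of detection. PDE6G, a subunit of the photoreceptor phosphodiesterase (chromosome 17, 81650459 to 81663112), had 0 to 4 counts per vehicle library and 702 to 833 per inhibitor library, or 27.3 ± 1.64 CPM, a fitted change of 8.75 ± 0.367 (adjusted p = 1.02e-14). The actin-bundling spindle protein MISP (7.72 ± 0.247), the epithelial transcription factor ELF3 (7.49 ± 0.283), the noncoding RNA LINC02870 (6.64 ± 0.278), the secreted protease inhibitor SLPI (6.55 ± 0.323) and CGA, the shared subunit of glycoprotein hormones (6.49 ± 0.272), followed, each with at most 15 counts in any vehicle library. These fold changes therefore depend on how the model treats small counts. Among the lowest were the Wnt ligand WNT5B (−5.43 ± 0.188), the serotonin receptor HTR1F (−4.64 ± 0.274), the channel subunit FAM155A (−4.51 ± 0.181), the inositol phosphatase INPP5A (−4.49 ± 0.135) and the proteoglycan GPC6 (−4.48 ± 0.201). Of these, ELF3, WNT5B, INPP5A and GPC6 overlap genes on the opposite strand. EIF3CL, a near-identical copy of EIF3C, was at −5.73 ± 1.30 (adjusted p = 0.000485, and 0.164 with limma-voom), and its counts are uncertain because reads can be split between the copies.

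Lists of the translation and mitochondrial machinery fell as groups in WT cells. Here and below, counts of list members are over all genes tested, and those adjusted over the list alone were the same unless given. The ribosomal protein list passed camera (adjusted p = 8.02e-24, and adjusted p = 0.390 with an estimated correlation). Ribosome biogenesis genes had 31 of 37 members lower and 2 higher (camera adjusted p = 6.49e-07, and adjusted p = 0.134 with an estimated correlation). The 60S assembly factor BOP1 was at −3.25 ± 0.0546 and the nucleolar chaperone NPM1 at −2.00 ± 0.0602. Mitochondrial ribosomal proteins had 56 of 76 lower and 8 higher (camera adjusted p = 5.33e-06, and adjusted p = 0.469 with an estimated correlation). MRPL12 was at −3.19 ± 0.0694. Nuclear-encoded subunits of complexes IV and V had 23 of 26 lower and 0 higher (25 lower adjusted over the list alone; camera adjusted p = 1.38e-05, and adjusted p = 0.466 with an estimated correlation). ATP5MC2 was at −1.09 ± 0.0578. Complex III had 6 of 9 lower (camera adjusted p = 0.0498, and adjusted p = 0.605 with an estimated correlation). Complex I had 24 of 37 lower and 3 higher (camera adjusted p = 0.00246, and adjusted p = 0.622 with an estimated correlation), although its median of −0.34 became 0.0085 with library totals alone. Mitochondrial chaperones and proteases had 14 of 18 lower and 4 higher (camera adjusted p = 0.00627, and adjusted p = 0.367 with an estimated correlation).

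The mRNAs encoded by mitochondrial DNA did not move together in WT cells. Of 13, 7 were lower and 4 higher, the list was not called (camera adjusted p = 0.354), and its median of −0.24 became 0.11 with library totals alone. MT-ATP6 went from 5246 ± 370 to 1141 ± 33.1 CPM (−2.20 ± 0.0766, n = 4 each) and MT-ND3 changed by −1.44 ± 0.0802. Coenzyme Q synthesis and quinone-linked dehydrogenase genes (10 of 18 lower, 4 higher; camera adjusted p = 0.262) and aspartate and glutamine metabolism (7 of 15 lower, 5 higher, or 6 higher adjusted over the list alone; camera adjusted p = 0.742) were not called, and both of their medians, −0.25 and −0.13, turned positive with library totals alone.

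Nucleotide and central metabolism genes were mostly lower in WT cells. Purine synthesis and salvage had 17 of 20 members lower and 2 higher (camera adjusted p = 1.03e-04, and adjusted p = 0.238 with an estimated correlation). Adenosine kinase ADK was at −3.26 ± 0.0845 and IMPDH2, which commits IMP to guanine nucleotides, at −1.41 ± 0.0521. Pyrimidine synthesis and salvage had 19 of 31 lower and 7 higher (camera adjusted p = 0.0046, and adjusted p = 0.271 with an estimated correlation). Thymidylate kinase DTYMK was at −2.39 ± 0.0631, the ectonucleotidase NT5E at −1.42 ± 0.0615 and UMP-CMP kinase CMPK1 at −1.10 ± 0.0452. DHODH, the mitochondrial enzyme that oxidises dihydroorotate, went from 18.1 ± 1.30 to 12.6 ± 1.37 CPM (−0.52 ± 0.0933, adjusted p = 3.83e-05), but was not called with library totals alone (−0.18, adjusted p = 0.0983). CAD, which carries out the first steps of the pathway, was at 196 ± 13.7 and 204 ± 10.2 CPM (0.06 ± 0.0576, adjusted p = 0.36), and UMPS, which makes UMP, at 101 ± 3.38 and 106 ± 5.34 CPM (0.07 ± 0.0679, adjusted p = 0.371). Both were called higher with library totals alone (0.40, adjusted p = 3.85e-06, and 0.41, adjusted p = 1.82e-05) and with a stricter filter (0.15, adjusted p = 0.0201, and 0.16, adjusted p = 0.0345). Glycolysis and lactate export had 18 of 24 lower and 4 higher (camera adjusted p = 0.00135, and adjusted p = 0.295 with an estimated correlation). The phosphofructokinases PFKP and PFKL were at −2.49 ± 0.0598 and −1.82 ± 0.0526 and the glucose transporter SLC2A1 at −1.29 ± 0.0468.

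The tricarboxylic acid cycle, fatty acid and cholesterol lists were also lower in WT cells, and UDP-sugar metabolism was not called. The tricarboxylic acid cycle had 16 of 24 lower and 5 higher (camera adjusted p = 0.0114, and adjusted p = 0.400 with an estimated correlation), fatty acid synthesis and desaturation 10 of 14 lower and 2 higher (camera adjusted p = 0.0106, and adjusted p = 0.351 with an estimated correlation), and cholesterol synthesis and uptake 19 of 24 lower and 4 higher (camera adjusted p = 0.0109, and adjusted p = 0.375 with an estimated correlation). UDP-sugar metabolism had 8 of 19 members on each side (camera adjusted p = 0.999). Extracellular matrix and TGF-beta targets had 18 of 26 lower and 6 higher (camera adjusted p = 0.0187, and adjusted p = 0.434 with an estimated correlation). The matrix metalloproteinase MMP14 was at −1.71 ± 0.0549.

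Targets of ATF4, hypoxia targets and interferon-stimulated genes rose as lists in WT cells, and the unfolded protein response list fell. Targets of the integrated stress response, the ATF4 programme, had 22 of 34 higher and 7 lower (8 lower adjusted over the list alone; camera adjusted p = 0.00699, and adjusted p = 0.271 with an estimated correlation). The glycoprotein hormone STC2 was at 1.81 ± 0.0511 and the transcription factor CEBPB at 1.79 ± 0.0563. Cytosolic tRNA synthetases, some of which ATF4 induces, had 14 of 20 lower and 3 higher (camera adjusted p = 0.0195, and adjusted p = 0.351 with an estimated correlation), although their median of −0.26 became 0.09 with library totals alone. FARSB was at −3.57 ± 0.0664 and AARS1 at 1.26 ± 0.0402. Interferon-stimulated genes had 20 of 29 higher and 3 lower (camera adjusted p = 7.38e-04, and adjusted p = 0.238 with an estimated correlation). PARP9 was at 2.52 ± 0.0804 and IRF7 at 2.23 ± 0.102. The interferon-stimulated genes OASL and IFIT3, named below for ScURA cells, did not rise in WT cells. OASL was at 11.7 ± 0.923 and 10.3 ± 0.721 CPM with vehicle and inhibitor, and IFIT3 at 19.4 ± 1.97 and 18.2 ± 0.753 CPM. Hypoxia targets had 16 of 22 higher and 5 lower (17 higher adjusted over the list alone; camera adjusted p = 0.00699, and adjusted p = 0.365 with an estimated correlation). The MYC antagonist MXI1 was at 2.01 ± 0.073 and NDRG1 at 1.44 ± 0.0758. The unfolded protein response of the endoplasmic reticulum had 15 of 22 lower and 5 higher (camera adjusted p = 0.0301, and adjusted p = 0.466 with an estimated correlation).

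Cell cycle genes were split in WT cells. DNA replication and G1/S genes had 26 of 38 lower and 3 higher (4 higher adjusted over the list alone; camera adjusted p = 5.84e-04, and adjusted p = 0.443 with an estimated correlation), although their median of −0.28 became 0.07 with library totals alone. The replication factor CDC45 was at −1.80 ± 0.0627 and the polymerase subunit POLA1 at −1.67 ± 0.0641. G2/M and mitosis genes had 15 of 31 lower and 11 higher (camera adjusted p = 0.82) and their median of −0.05 became 0.30 with library totals alone. Targets of p53 (12 of 24 higher, 8 lower; camera adjusted p = 0.45), NF-kB (10 of 20 higher, 8 lower; camera adjusted p = 0.665), NRF2 (7 of 19 higher, 9 lower; camera adjusted p = 0.78) and TFEB (14 of 27 higher, 11 lower; camera adjusted p = 0.596) and osteoblast lineage genes (8 of 10 higher, 1 lower; camera adjusted p = 0.0943) were not called. The NRF2 median of −0.02 became 0.32 with library totals alone, and those of p53 and TFEB targets went from 0.22 to 0.57 and from 0.14 to 0.48. Among markers of other cell types, 7 of 8 epithelial markers were higher (camera adjusted p = 0.0239, and adjusted p = 0.238 with an estimated correlation). Keratin KRT8 was at 1.28 ± 0.0519 and EPCAM at 1.11 ± 0.117. Endothelial (2 of 4 higher, 1 lower; camera adjusted p = 0.731), leukocyte (camera adjusted p = 0.441) and neural markers (1 of 3 higher, 1 lower; camera adjusted p = 0.852) were not called. None of the 21 lists called in WT cells held with an estimated correlation, and fry called 32 of the 34. With library totals alone the calls of complexes I and III, the tricarboxylic acid cycle, cholesterol synthesis, tRNA synthetases, the unfolded protein response, DNA replication genes and epithelial markers were lost (adjusted p between 0.0702 and 0.591). That scaling also moved the counts of many lists: lower and higher members became 33 and 28 for mitochondrial ribosomal proteins, 12 and 14 for complex I, 4 and 4 for complex III, 11 and 10 for the tricarboxylic acid cycle, 13 and 8 for glycolysis, 8 and 8 for cholesterol synthesis, 7 and 10 for tRNA synthetases, 15 and 16 for DNA replication genes and 5 and 21 for G2/M genes. Without WT vehicle replicate 4 or WT inhibitor replicate 3, 5 mitochondrial ribosomal proteins were higher instead of 8. Complex III was also not called with DESeq2 size factors (adjusted p = 0.0596) or without WT inhibitor replicate 1, 2 or 4 or WT vehicle replicate 1 or 3 (adjusted p between 0.0514 and 0.0662).

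In ScURA cells the same inhibitors were accompanied by a strong ATF4 target response, lower DNA replication genes and lower interferon-stimulated genes, while ribosomal protein mRNAs rose slightly. Of 34 integrated stress response targets, 29 were higher and 3 lower, with a median of 1.09 (camera adjusted p = 3.83e-11, and adjusted p = 0.0158 with an estimated correlation), the only list called in this comparison that held with an estimated correlation. All but 2 of the 38 DNA replication and G1/S genes were lower and 0 were higher (camera adjusted p = 1.06e-14, and adjusted p = 0.162 with an estimated correlation). Ribosomal proteins had 64 of 74 higher and 1 lower (66 higher adjusted over the list alone), with a median of 0.27 (camera adjusted p = 3.42e-07, and adjusted p = 0.628 with an estimated correlation), and EEF1A1 went from 11920 ± 620 to 18190 ± 1040 CPM (0.61 ± 0.0661, n = 4 each). Of 17980 genes tested, 5655 were higher and 5506 lower, 62.1% in all, and 2005 and 1069 of them changed at least 2-fold.

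The heat shock gene HSPA6 and the cytokine gene GDF15 were at the top of the increases in ScURA cells. HSPA6, an inducible heat shock protein, rose by 7.37 ± 0.718 (adjusted p = 1.86e-08), but it had 0 to 4 counts per vehicle library and 123 to 984 per inhibitor library and was not called by limma-voom (adjusted p = 0.0517). GDF15, a secreted stress cytokine, went from 0.937 to 23.2 ± 5.74 CPM (4.58 ± 0.227, adjusted p = 9.74e-13), and it was at 1.71 and 24.4 ± 1.53 CPM in WT cells. The others were YPEL2 (3.95 ± 0.203), ELF3 (3.91 ± 0.385), the activin subunit INHBE (3.56 ± 0.353) and the mTORC1 regulator DDIT4 (3.45 ± 0.0883), which overlaps an antisense gene. ELF3 had 0 to 2 counts per vehicle library and 18 to 54 per inhibitor library, and INHBE 1 to 4 and 30 to 65. Both fold changes thus rest on small counts. ELF3 was at 1.44 CPM in ScURA inhibitor and 17.6 CPM in WT inhibitor libraries, and INHBE at 2.03 and 11.6 CPM. Among ATF4 targets, asparagine synthetase ASNS was at 2.66 ± 0.058, PCK2 at 2.53 ± 0.0572 and the mitochondrial folate enzyme ALDH1L2 at 2.90 ± 0.0729, and DDIT3 went from 4.95 ± 0.553 to 23.1 ± 4.65 CPM. Cytosolic tRNA synthetases had 12 of 20 higher and 5 lower (camera adjusted p = 0.00417, and adjusted p = 0.238 with an estimated correlation). AARS1 was at 1.14 ± 0.0406 and SARS1 at 1.10 ± 0.0418. Thrombospondin THBS1 was at −2.55 ± 0.0506, and the matrix list as a whole was not called (9 of 26 higher, 8 lower, 10 higher adjusted over the list alone; camera adjusted p = 0.63).

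Interferon-stimulated genes led the decreases in ScURA cells. OASL, an oligoadenylate synthetase-like protein (chromosome 12, 121019111 to 121039242), went from 54.9 ± 4.02 to 2.67 ± 1.48 CPM (−4.31 ± 0.189, adjusted p = 1.91e-13, n = 4 each). IFIT3 was at −3.73 ± 0.158, IFIT1 at −3.73 ± 0.155 and IFIT2 at −3.40 ± 0.223, and all 3 overlap LIPA on the opposite strand. The adaptor DOK3 (−3.43 ± 0.239) and the gelatinase MMP9 (−3.27 ± 0.23), which overlap antisense genes, were the others at this end. The interferon list had 18 of 29 lower and 3 higher (19 and 4 adjusted over the list alone; camera adjusted p = 1.78e-04, and adjusted p = 0.238 with an estimated correlation). NF-kB targets went the other way, with 14 of 20 higher and 4 lower (camera adjusted p = 0.00298, and adjusted p = 0.422 with an estimated correlation), including the cytokine IL1B, which rose from 17.8 ± 2.42 to 114 ± 10.7 CPM (2.69 ± 0.136), and NFKB2 (1.23 ± 0.0629).

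Proliferation and nucleolar genes were lower in ScURA cells with inhibitor. The replication protein RPA2 was at −1.28 ± 0.0511, MCM10 at −1.46 ± 0.067 and MCM3 at −1.02 ± 0.0473. G2/M and mitosis genes had 25 of 31 lower and 0 higher (1 higher adjusted over the list alone; camera adjusted p = 4.39e-06, and adjusted p = 0.351 with an estimated correlation). Survivin BIRC5 was at −1.20 ± 0.0578 and the kinase AURKA at −0.89 ± 0.0437. Ribosome biogenesis genes had 31 of 37 lower and 1 higher (camera adjusted p = 9.45e-10, and adjusted p = 0.0593 with an estimated correlation). Nucleolin NCL was at −0.84 ± 0.0361 and the RNA polymerase I factor UBTF at −1.05 ± 0.0499. Among ribosomal proteins, RPL3 was at 0.48 ± 0.0462, and RPS26, the 1 member that fell, at −0.73 ± 0.0622. The p53 list was not called (12 of 24 higher, 7 lower; camera adjusted p = 0.232). BBC3 was at 3.26 ± 0.155 and CDKN1A at 0.80 ± 0.0521.

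UMPS was the enzyme of UMP synthesis that changed in ScURA cells. It fell from 102 ± 6.46 to 46.6 ± 6.08 CPM (−1.11 ± 0.0715, adjusted p = 3.88e-11, n = 4 each), whereas DHODH stood at 17.5 ± 1.15 and 17.4 ± 1.92 CPM (0.00 ± 0.0945, adjusted p = 0.992) and CAD at 200.3 ± 14 and 194 ± 10.5 CPM (−0.05 ± 0.0582, adjusted p = 0.472). The pyrimidine list had 19 of 31 lower and 4 higher (camera adjusted p = 0.00388, and adjusted p = 0.267 with an estimated correlation). Thymidylate synthase TYMS was at −0.69 ± 0.0424 and NT5E at −1.41 ± 0.0623, while uridine phosphorylase UPP1 was at 1.82 ± 0.0485. Purine genes were not called (11 of 20 lower, 3 higher; camera adjusted p = 0.222). Mitochondrial ribosomal proteins had 46 of 76 lower and 10 higher, or 6 higher without ScURA vehicle replicate 1 (camera adjusted p = 1.36e-04, and adjusted p = 0.598 with an estimated correlation), and mRNAs of mitochondrial DNA 8 of 13 lower and 2 higher (camera adjusted p = 0.0155, and adjusted p = 0.620 with an estimated correlation). MT-CYB was at −1.58 ± 0.0833, MT-ND2 at −1.34 ± 0.0778 and MT-CO3 at −0.72 ± 0.0529. Hypoxia targets had 15 of 22 higher and 4 lower (camera adjusted p = 0.00424, and adjusted p = 0.351 with an estimated correlation). NDRG1 was at 2.22 ± 0.0756. Osteoblast lineage genes had 9 of 10 higher and 1 lower (camera adjusted p = 0.00612, and adjusted p = 0.238 with an estimated correlation), and NRF2 targets 11 of 19 higher and 4 lower (camera adjusted p = 0.0411, and adjusted p = 0.400 with an estimated correlation). The remaining lists were not called, although mitochondrial chaperones and proteases were without ScURA vehicle replicate 1 (adjusted p = 0.0411). Among them were complex I (11 of 37 lower, 4 higher, but 7 lower without ScURA inhibitor replicate 3, 7 higher without ScURA inhibitor replicate 1, 2 higher without ScURA vehicle replicate 4, and 5 lower and 9 higher with library totals alone; camera adjusted p = 0.714), complex III (3 of 9 on each side; camera adjusted p = 0.989), complexes IV and V (7 of 26 lower, 6 higher, 5 and 5 adjusted over the list alone; camera adjusted p = 0.918), glycolysis (14 of 24 lower, 8 higher; camera adjusted p = 0.242) and the tricarboxylic acid cycle (5 of 24 on each side; camera adjusted p = 0.964). Fry called 27 of the 34 lists.

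**Figure D2:**
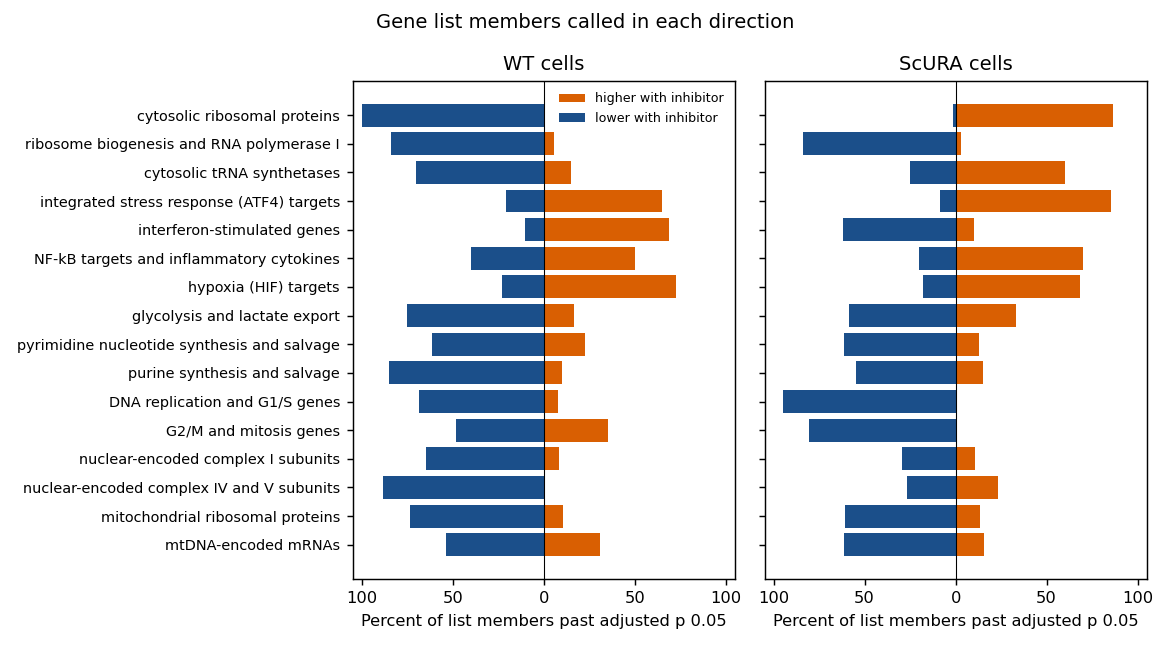
Bars give, for 16 of the gene lists, the percent of members called higher (orange, to the right of 0) or lower (blue, to the left) with inhibitor against vehicle at an adjusted p under 0.05, in WT cells (left panel) and ScURA cells (right panel). All 74 ribosomal proteins were lower in WT cells and 64 were higher in ScURA cells. With library totals alone the median turned positive in WT cells for tRNA synthetases, DNA replication genes, G2/M genes, complex I and mitochondrial mRNAs, and in ScURA cells for complex I and complexes IV and V.

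The difference between both responses was tested directly, and cytosolic ribosomal proteins and interferon-stimulated genes differed in opposite directions. All 74 ribosomal protein mRNAs had a more positive response in ScURA than in WT cells, with a median difference of 1.67 (camera adjusted p = 4.02e-29, and adjusted p = 0.351 with an estimated correlation), including RPL23 (2.91 ± 0.0898) and RPL4 (2.62 ± 0.0763), and EEF1A1 differed by 3.42 ± 0.0958 (adjusted p = 1.34e-16). In the opposite direction, 28 of 29 interferon-stimulated genes had a more negative response in ScURA cells, with a median difference of −2.04 (camera adjusted p = 9.45e-10, and adjusted p = 0.0593 with an estimated correlation), including IFIT1 (−3.91 ± 0.205), PARP9 (−2.82 ± 0.117) and ISG15 (−2.75 ± 0.15). Of 17980 genes, 5672 had a more positive and 6037 a more negative response in ScURA cells, 65.1% in all, and 2600 and 3023 differed at least 2-fold. More positive responses were 48.4% of the calls, and 32.9% (3996 against 8139) with library totals alone.

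The zinc finger gene ZNF25 (5.54 ± 0.284), the recombination gene RAD51B (5.48 ± 0.249), WNT5B (4.86 ± 0.238) and FAM155A (4.55 ± 0.228) were among the genes with the most positive differences, together with the uncertain EIF3CL (4.89 ± 1.62, adjusted p = 0.0122), which was not called with DESeq2 (adjusted p = 0.0817), limma-voom (0.418) or the normalized counts deposited by the authors (0.0831). The most negative were the pseudogene AADACP1 (−8.56 ± 0.701), SLPI (−8.45 ± 0.636), the sarcomere protein MYPN (−6.91 ± 0.49), MISP (−6.82 ± 0.872), LINC02870 (−6.28 ± 0.963) and CGA (−6.20 ± 0.988). These 6 had at most 28 counts in any vehicle library and at most 15 in any ScURA inhibitor library. UMPS differed by −1.18 ± 0.0985 (adjusted p = 1.47e-09, and 0.059 with the normalized counts deposited by the authors), DHODH by 0.52 ± 0.133 (adjusted p = 0.00177, and 0.122 with library totals alone) and CAD by −0.11 ± 0.0818 (adjusted p = 0.253), although CAD was called with library totals alone (−0.39, adjusted p = 0.000434).

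**Figure D3:**
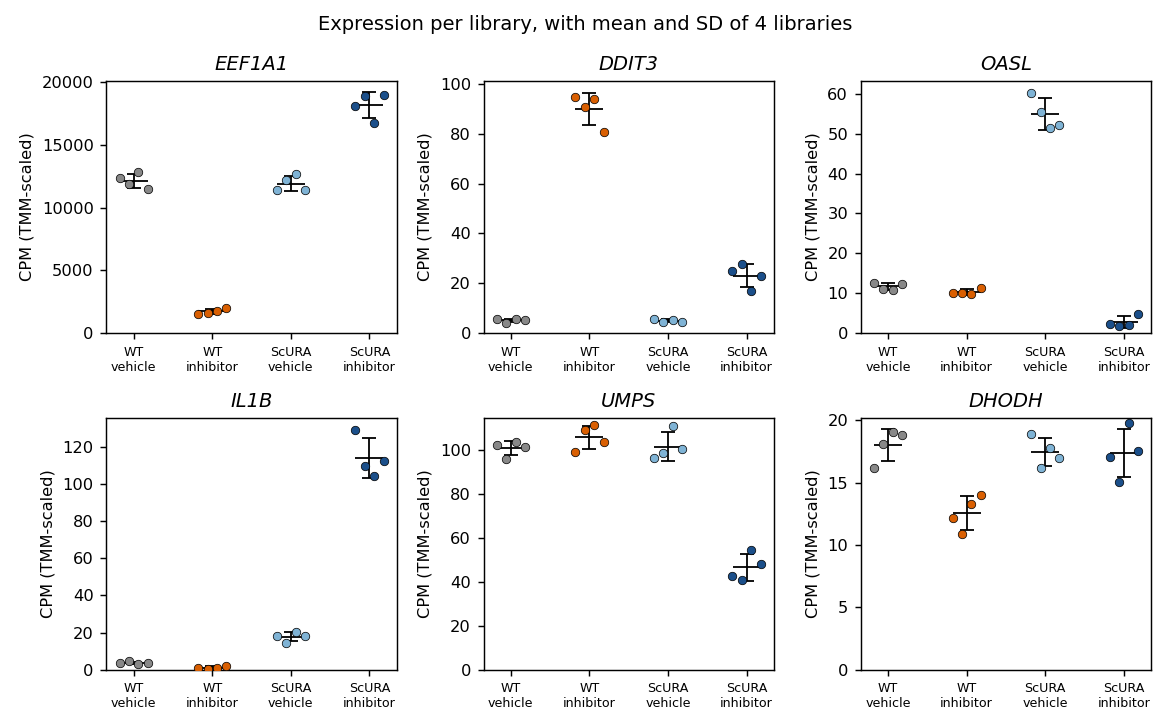
Points give CPM after TMM scaling in each library for EEF1A1, DDIT3, OASL, IL1B, UMPS and DHODH (1 panel each, vertical axis in CPM from 0), and lines give the mean and SD of the 4 libraries of a group. EEF1A1 was at 1730 ± 221 CPM in WT inhibitor and 18190 ± 1040 in ScURA inhibitor libraries, and UMPS at 106 ± 5.34 and 46.6 ± 6.08.

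Further lists differed between the responses. Responses were more positive in ScURA cells for 15 of 20 tRNA synthetases and more negative for 2 (camera adjusted p = 4.43e-05, and adjusted p = 0.134 with an estimated correlation). FARSB differed by 3.34 ± 0.087 and SARS1 by 1.45 ± 0.0589. Purine genes had 16 of 20 members more positive and 2 more negative (camera adjusted p = 1.07e-04, and adjusted p = 0.238 with an estimated correlation), among them ADK (3.13 ± 0.111) and IMPDH2 (1.16 ± 0.0724). Subunits of complexes IV and V had 24 of 26 more positive and 0 more negative (camera adjusted p = 1.61e-05, and adjusted p = 0.466 with an estimated correlation). Glycolysis had 16 of 24 more positive and 3 more negative (camera adjusted p = 0.00469, and adjusted p = 0.351 with an estimated correlation), among them PFKP (2.21 ± 0.0807) and PFKL (2.11 ± 0.0718). The unfolded protein response had 15 of 22 more positive and 3 more negative (camera adjusted p = 0.0061, and adjusted p = 0.400 with an estimated correlation), and cholesterol synthesis 16 of 24 and 4 (camera adjusted p = 0.0187, and adjusted p = 0.400 with an estimated correlation). The matrix list had 14 of 26 more positive and 7 more negative (camera adjusted p = 0.041, and adjusted p = 0.466 with an estimated correlation), and its member CCN2 differed by 3.20 ± 0.0938. Complex I had 19 of 37 more positive and 2 more negative (camera adjusted p = 0.00944, and adjusted p = 0.666 with an estimated correlation), but its median of 0.28 became −0.0057 with library totals alone. The tricarboxylic acid cycle had 14 of 24 more positive and 5 more negative (camera adjusted p = 0.0172, and adjusted p = 0.412 with an estimated correlation), and its median of 0.28 became −0.0040 with that scaling.

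Cell cycle lists had more negative responses in ScURA cells. Of 31 G2/M genes, 21 were more negative and 5 more positive (22 and 5 adjusted over the list alone), with AURKA at −1.01 ± 0.061 (camera adjusted p = 0.00231, and adjusted p = 0.459 with an estimated correlation). Of 38 DNA replication genes, 22 were more negative and 8 more positive (camera adjusted p = 0.0109, and adjusted p = 0.596 with an estimated correlation). The transcription factors E2F1 and E2F2 differed by −2.12 ± 0.114 and −2.40 ± 0.111. The integrated stress response list was not called for a difference, with 17 of 34 members more positive and 10 more negative, or 20 and 11 adjusted over the list alone (camera adjusted p = 0.0501). Its members ALDH1L2 and MTHFD2 differed by 2.22 ± 0.102 and 1.82 ± 0.0622. The pyrimidine list was not called either, with 16 of 31 more positive and 7 more negative (camera adjusted p = 0.0611), and UPP1 differed by 1.71 ± 0.0676. Mitochondrial mRNAs differed both ways, 7 of 13 more positive and 6 more negative (camera adjusted p = 0.926). MT-ATP6, at 5660 ± 397 and 3353 ± 473 CPM in ScURA vehicle and inhibitor libraries, differed by 1.45 ± 0.104, and MT-ND2 by −1.72 ± 0.109. None of the 13 lists called held with an estimated correlation, and fry called 30. With library totals alone the calls of cholesterol synthesis, glycolysis, complex I and the tricarboxylic acid cycle were lost (adjusted p between 0.116 and 0.173), and without WT inhibitor replicate 4 that of the matrix list (0.0529). With library totals alone the more positive and more negative members numbered 9 and 6 for cholesterol synthesis, 8 and 9 for glycolysis, 14 and 14 for complex I, 9 and 7 for the tricarboxylic acid cycle, 13 and 0 for complexes IV and V, 10 and 12 for the pyrimidine list and 19 and 34 for mitochondrial ribosomal proteins. The integrated stress response list was called without any 1 of 10 libraries, namely every ScURA vehicle library, ScURA inhibitor replicates 1 and 2, WT inhibitor replicate 3 and WT vehicle replicates 2, 3 and 4 (adjusted p between 0.0355 and 0.0488). The pyrimidine list was called without any 1 of 7, namely ScURA inhibitor replicates 1, 2 and 4, ScURA vehicle replicates 2 and 3 and WT vehicle replicates 2 and 4 (0.0467 to 0.049). Mitochondrial ribosomal proteins had 34 of 76 more positive and 15 more negative and were not called (camera adjusted p = 0.0521), but were without any 1 of 9 libraries, namely every ScURA inhibitor library, ScURA vehicle replicates 2 and 3, WT inhibitor replicate 3 and WT vehicle replicates 2 and 4 (0.0149 to 0.0494). Their median of 0.12 became −0.16 with library totals alone. Complex III had 6 of 9 more positive and 1 more negative (camera adjusted p = 0.077) and was called without WT inhibitor replicate 3 (0.041).

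Across all genes the responses of both genotypes were related. Log2 fold changes correlated with r = 0.256 and a Spearman rho of 0.280 across 17980 genes, which are not independent replicates, and the comparisons share no library. Both responses were called higher for 2955 genes and both lower for 3136, against 2235.9 and 2054.5 for independent lists, while 1266 were higher in WT and lower in ScURA cells and 1572 the reverse, against 2177 and 2110.1. Among the 13579 genes called for the mean of both responses, 65.1% (jackknife SE 1.89) had the larger response in WT cells, with a median absolute log2 fold change of 0.78 against 0.49, and the slope of ScURA on WT responses was 0.339 (jackknife SE 0.0721). The jackknife took the 16 libraries as 1 sample, although they form 4 groups, so these SEs are rough. With 1 library left out the share ran from 64.1% to 65.9%. The slope then ran from 0.334 to 0.392, mostly above the full value. Reassigning the genotype labels within each treatment did not settle whether chance gives such a share. The choice of genes mattered, since genes called in WT cells gave 75.0% and a slope of 0.210, and genes called in ScURA cells 49.1% and 0.623.

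**Figure D4:**
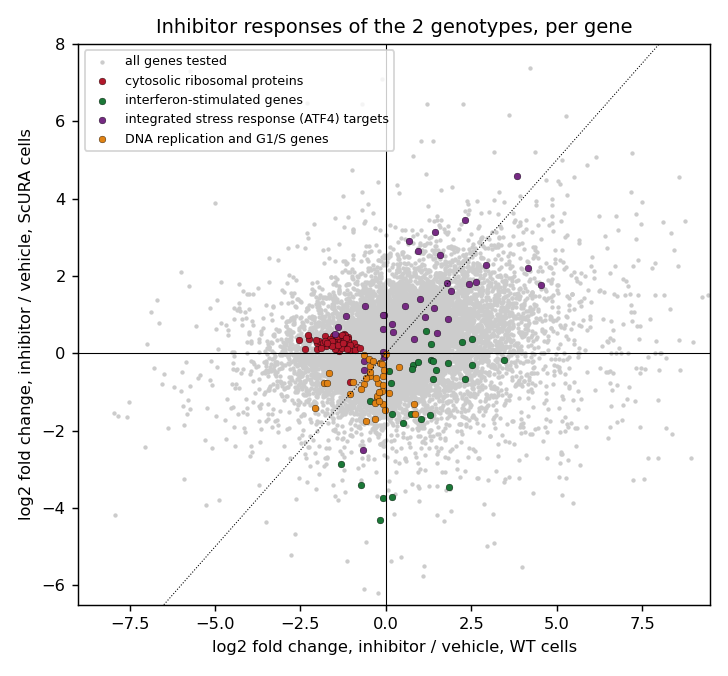
Each grey point is a gene, placed by its log2 fold change with inhibitor in WT cells (horizontal axis) and in ScURA cells (vertical axis), with members of 4 lists in colour and the line of equal response dotted; 10 genes lie outside the axes. Ribosomal proteins (red) lie left of 0 and mostly above 0, interferon-stimulated genes (green) are mostly right of 0 and below 0, and DNA replication genes (orange) are below 0; with library totals alone the WT median of the DNA replication genes turned positive.

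Without inhibitor, interferon-stimulated genes were higher in ScURA than in WT cells. OASL was at 54.9 ± 4.02 against 11.7 ± 0.923 CPM (2.23 ± 0.16, adjusted p = 2.87e-08) and IFIT1 at 35.5 ± 0.660 against 11 ± 1.91 CPM (1.69 ± 0.133), with n = 4 each. The NF-kB target IL1B was also higher, at 17.8 ± 2.42 against 3.67 ± 0.703 CPM (2.26 ± 0.176, n = 4 each). Of 29 interferon-stimulated genes 17 were higher and 0 lower (18 higher adjusted over the list alone). Their median was 0.78 (camera adjusted p = 1.27e-23, and adjusted p = 0.00357 with an estimated correlation), the only list of this comparison that held with an estimated correlation. ISG15 was at 1.38 ± 0.106, SAMD9 at 1.36 ± 0.0958 and HERC6 at 1.30 ± 0.0969. The other highest genes were IFI44 (1.69 ± 0.139), MMP9 (1.66 ± 0.206) and IFIT2 (1.63 ± 0.197). Among the lowest were LINC00707 (−1.30 ± 0.163), the phosphatase ALPP (−1.26 ± 0.221, adjusted p = 0.00117, and 0.221 with the normalized counts deposited by the authors), the neuropeptide receptor VIPR1 (−1.11 ± 0.0797), TM4SF18 (−1.10 ± 0.123) and NOTCH2NLB (−1.05 ± 0.218), whose reads can be shared with near-identical copies. Of these, ALPP, VIPR1, TM4SF18, MMP9 and IFIT2 overlap genes on the opposite strand. None of the 3 enzymes of UMP synthesis was called, with DHODH at −0.05 ± 0.0948 (adjusted p = 0.842), CAD at 0.04 ± 0.0582 (0.816) and UMPS at 0.01 ± 0.0691 (0.97).

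Few genes differed between the vehicle groups. Of 17980, 674 were higher and 414 lower in ScURA cells, 6.05% in all, and 62 and 52 differed at least 2-fold. These counts depended on single libraries and on the table used. Without WT vehicle replicate 3 they were 449 and 248. The lower count was 274 without WT vehicle replicate 2, 249 without ScURA vehicle replicate 1 and 273 without ScURA vehicle replicate 4. The normalized counts deposited by the authors gave 231 and 116.

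Smaller shifts in other lists separated the vehicle groups, none of which held with an estimated correlation. The fold changes of 13897 coding genes in this comparison also correlated with transcript GC content (Spearman 0.178, against 0.0547 for the WT inhibitor response). Whether GC content has a part in these list shifts was not tested. Glycolysis genes had 10 of 24 members higher and 0 lower (13 higher adjusted over the list alone; camera adjusted p = 1.11e-06, and adjusted p = 0.134 with an estimated correlation). LDHA was at 0.24 ± 0.0422 and PGK1 at 0.24 ± 0.0393, the latter not called with the normalized counts deposited by the authors (adjusted p = 0.0607). Hypoxia targets had 8 of 22 higher and 1 lower (12 and 2 adjusted over the list alone; camera adjusted p = 1.82e-05, and adjusted p = 0.174 with an estimated correlation). VEGFA was at 0.44 ± 0.0425. Matrix genes had 11 of 26 higher and 1 lower (13 and 4 adjusted over the list alone; camera adjusted p = 1.38e-05, and adjusted p = 0.238 with an estimated correlation). COL5A1 was at 0.95 ± 0.0893, TGFBI at 0.79 ± 0.0349 and COL6A2 at 0.73 ± 0.0605. The unfolded protein response had 10 of 22 higher (11 adjusted over the list alone; camera adjusted p = 3.35e-06, and adjusted p = 0.238 with an estimated correlation), with PDIA4 at 0.33 ± 0.0419. UDP-sugar metabolism had 4 of 19 higher (6 adjusted over the list alone; camera adjusted p = 6.08e-04, and adjusted p = 0.115 with an estimated correlation). GFPT2 was at 0.49 ± 0.0416. NF-kB targets had 9 of 20 higher and 1 lower (10 and 3 adjusted over the list alone; camera adjusted p = 7.76e-04, and adjusted p = 0.400 with an estimated correlation). ICAM1 was at 0.44 ± 0.0556. G2/M genes had 5 of 31 lower (8 adjusted over the list alone; camera adjusted p = 7.19e-06, and adjusted p = 0.351 with an estimated correlation). NUSAP1 was at −0.22 ± 0.0432 and CDK1 at −0.25 ± 0.0581. The normalized counts deposited by the authors called neither NUSAP1 (adjusted p = 0.29) nor CDK1 (0.507), and CDK1 was not called without WT vehicle replicate 3 (0.0526). NRF2 targets had 5 of 19 lower and 1 higher (6 and 2 adjusted over the list alone; camera adjusted p = 0.0152, and adjusted p = 0.365 with an estimated correlation). NQO1 was at −0.44 ± 0.0548. These counts depended on single libraries. Glycolysis had 5 members higher without WT vehicle replicate 3, and 6 without WT vehicle replicate 2 or ScURA vehicle replicate 1, 2 or 4. The unfolded protein response had 5 higher without WT vehicle replicate 4 and 6 without WT vehicle replicate 3, G2/M genes had 3 lower without WT vehicle replicate 3 or ScURA vehicle replicate 1, and NRF2 targets 3 lower without ScURA vehicle replicate 1. With the normalized counts deposited by the authors, glycolysis, hypoxia targets and the unfolded protein response each had 3 higher, matrix genes 4 higher, NRF2 targets 3 lower and G2/M genes 0 lower. Further calls rested on small medians. Cytosolic ribosomal proteins were at −0.07 (camera adjusted p = 7.76e-04, and adjusted p = 0.767 with an estimated correlation), mitochondrial ribosomal proteins at −0.06 (camera adjusted p = 0.012, and adjusted p = 0.740 with an estimated correlation) and complex I at −0.06 (camera adjusted p = 0.0211, and adjusted p = 0.716 with an estimated correlation). Complexes IV and V were at −0.06 (camera adjusted p = 0.0253, and adjusted p = 0.743 with an estimated correlation) and mitochondrial mRNAs at 0.14 (camera adjusted p = 0.00135, and adjusted p = 0.466 with an estimated correlation). The first 4 of these calls were lost without WT vehicle replicate 1 and without ScURA vehicle replicate 4 (adjusted p between 0.051 and 0.23), all of them but the first without WT vehicle replicate 3 (0.135 to 0.166), and complex I without ScURA vehicle replicate 1 (0.0548). Fry called none of the 5 and 13 of all 34 lists.

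With inhibitor, ScURA and WT cells differed at 13837 genes, 6484 higher and 7353 lower in ScURA cells, 77.0% of those tested, and 2796 and 3630 differed at least 2-fold. Higher genes were 46.9% of the calls, and 32.7% (4635 against 9554) with library totals alone. IL1B was at 114 ± 10.7 CPM in ScURA against 1.15 ± 0.653 CPM in WT cells (6.64 ± 0.183, adjusted p = 1.47e-17, n = 4 each). ZNF25 (5.35 ± 0.22), RAD51B (5.03 ± 0.195), the cytokine CSF3 (4.75 ± 0.215) and the survival factor BCL2A1 (4.71 ± 0.172) were also at this end. At the other were AADACP1 (−8.33 ± 0.367), CGA (−7.35 ± 0.293), MYPN (−7.33 ± 0.221), LINC02870 (−7.18 ± 0.29), PDE6G (−6.94 ± 0.302) and MISP (−6.94 ± 0.226). UMPS was lower in ScURA cells (−1.17 ± 0.0704, adjusted p = 3.41e-12). DHODH was higher (0.47 ± 0.0931, adjusted p = 0.000116), but not with library totals alone (0.18, adjusted p = 0.0886). CAD was at −0.07 ± 0.0575 (adjusted p = 0.254), and was called with library totals alone (−0.36, adjusted p = 1.36e-05) and with a stricter filter (−0.14, adjusted p = 0.0323).

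Under inhibitor all 74 ribosomal proteins were higher in ScURA than in WT cells, with a median of 1.59 (camera adjusted p = 7.52e-26, and adjusted p = 0.365 with an estimated correlation), and 25 of 29 interferon-stimulated genes were lower and 0 higher, with a median of −1.29 (camera adjusted p = 1.12e-05, and adjusted p = 0.155 with an estimated correlation). Higher in ScURA cells were 17 of 20 purine genes, with 2 lower (camera adjusted p = 1.02e-04, and adjusted p = 0.238 with an estimated correlation), 19 of 24 glycolysis genes, with 1 lower (camera adjusted p = 1.68e-04, and adjusted p = 0.238 with an estimated correlation), and 15 of 20 tRNA synthetases, with 3 lower (camera adjusted p = 1.95e-04, and adjusted p = 0.162 with an estimated correlation). G2/M genes had 23 of 31 lower and 3 higher (24 lower adjusted over the list alone; camera adjusted p = 2.76e-04, and adjusted p = 0.400 with an estimated correlation). Camera called 14 lists in this comparison, none of which held with an estimated correlation, and fry called 31. Of the 14, complex I and fatty acid synthesis were not called with DESeq2 size factors (adjusted p = 0.0561 and 0.0524). Complex I was also not called without WT inhibitor replicate 1, 2 or 4 (0.0514 to 0.0785), nor fatty acid synthesis without WT inhibitor replicate 1 or 3 (0.052 and 0.0553), and library totals alone ended both calls and those of cholesterol synthesis and the tricarboxylic acid cycle (0.119 to 0.454) and left 12 glycolysis genes higher and 7 lower.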

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

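The test of the GC content bound, the test of scaling between libraries and the comparison of interferon-stimulated genes with separate ScURA vehicle libraries were chosen after the result was seen, as were scaling by library totals alone and list tests without mitochondrial genes.

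On the single measures tested, few libraries stood apart within their group of 4. Dixon's test at the 95% level was applied to 80 groups and passed in 7, where chance gives about 4. WT inhibitor replicate 1 had 26048933 estimated counts, against 23237525 to 23681184 in the other replicates. The 10 most abundant genes took 5.78% of the counts of WT vehicle replicate 1, against 6.19% to 6.27%, and its MT-ATP6 level was 4695 CPM, against 5373 to 5482. The TMM factor of WT inhibitor replicate 3 was 1.18, against 1.19. PDE6G was at 0.0679 CPM in ScURA vehicle replicate 1 and at 0 in the others. OASL was at 11.4 CPM in WT inhibitor replicate 4, against 9.81 to 10.0, and CAD at 178 CPM in ScURA inhibitor replicate 4, against 197 to 200.4. Larger departures lay outside that test. On principal component 3 (3.61% of the variance) ScURA vehicle replicate 3 lay at −61.1, against −9.87 to 17.5 in its group. Chi-square per degree of freedom was 10.3 to 15.5 for pairs with ScURA inhibitor replicate 3, the deepest library, and 3.90 to 7.69 for other pairs of that group.

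The inhibitor response differed between genotypes by edgeR's test of the difference itself (ScURA minus WT, log2 scale), more positive for 5672 and more negative for 6037 genes. In the translation machinery RPL23 differed by 2.91, RPL4 by 2.62, EEF1A1 by 3.42, FARSB by 3.34 and SARS1 by 1.45. Of the nucleotide and folate enzymes, ADK differed by 3.13, IMPDH2 by 1.16, UPP1 by 1.71, DHODH by 0.52, UMPS by −1.18, MTHFD2 by 1.82 and ALDH1L2 by 2.22. Interferon-stimulated genes were more negative, with IFIT1 at −3.91, PARP9 at −2.82 and ISG15 at −2.75, as were E2F1 (−2.12), E2F2 (−2.40) and AURKA (−1.01). Of the energy metabolism genes, PFKL differed by 2.11, PFKP by 2.21, COX7C by 1.249, MT-ATP6 by 1.45 and MT-ND2 by −1.72, and the matrix gene CCN2 by 3.20. The remaining genes were ZNF25 (5.54), RAD51B (5.48), EIF3CL (4.89), WNT5B (4.86), FAM155A (4.55), AADACP1 (−8.56), SLPI (−8.45), MYPN (−6.91), MISP (−6.82), LINC02870 (−6.28) and CGA (−6.20). DHODH was not called with library totals alone (0.24, adjusted p = 0.122). EIF3CL was not called with DESeq2 (adjusted p = 0.0817), limma-voom (0.418) or limma on the normalized counts deposited by the authors (0.0831), nor UMPS with the last (0.059).

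Gene lists called by camera for this difference had medians of 1.67 for cytosolic ribosomal proteins, 0.83 for tRNA synthetases, 0.60 for matrix genes, 0.56 for purine synthesis, 0.50 for complexes IV and V, 0.43 for the unfolded protein response, 0.34 for cholesterol synthesis, 0.32 for glycolysis, 0.28 for the tricarboxylic acid cycle and 0.28 for complex I. Medians were −2.04 for interferon-stimulated genes, −0.39 for G2/M genes and −0.37 for DNA replication genes. With library totals alone the medians of complex I and the tricarboxylic acid cycle became −0.0057 and −0.0040. None of these calls held with an estimated correlation (adjusted p between 0.0593 and 0.666). With library totals alone those of cholesterol synthesis, glycolysis, complex I and the tricarboxylic acid cycle were lost (0.116 to 0.173), and without WT inhibitor replicate 4 that of matrix genes (0.0529).

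Other splits of the same libraries were tested for as many calls. Each comparison of 2 groups was refitted on its own 8 libraries with lists adjusted over that comparison, and for the difference between responses 100 assignments of the genotype within each treatment were used. For genes, the real split called the most in every comparison: 13711 in WT cells (highest of the other splits 0), 10494 in ScURA cells (0), 1131 under vehicle (2) and 13696 under inhibitor (0), each matched by 1 of 35 splits, the real one, and 11709 for the difference (11569), matched by 1 of 100. A chance division of these libraries is thus argued against. Chance differences between cultures are not, because the libraries of a group need not be separate cultures. For the difference the gene count is a weak measure too, since the assignments nearest to it kept both inhibitor groups whole. For lists, the real split called the most in WT cells (21, highest other 20), in ScURA cells (13 and 10) and under vehicle (14 and 12), each with 1 of 35 splits as large. These highest other splits kept 6 of the 8 libraries together, and splits that kept only 4 together still called up to 8, 6 and 9 lists. With such margins, the smallest being 21 against 20, chance was not firmly excluded for these list counts. Chance was not excluded for lists under inhibitor (13, highest other 15, 4 of 35 splits as large) or for the difference (13, highest other 17, 12 of 100). Nor was it for the share of genes with the larger response in WT cells (65.13%, farthest other 32.54%), since 21 of 100 assignments gave a share as far from 50%. These 2 counts for the difference are a weak measure of chance, because the 11 other assignments with as many lists and the 20 with such a share all kept 6 or 8 of the inhibitor libraries together, and 0 of the 49 that kept only 4 together were among them. The 3 other splits under inhibitor with as many lists also kept 6 of the 8 libraries together. Of the other assignments, 5 kept both inhibitor groups whole, under their own or the exchanged genotype, and called 11438 to 11569 genes, and the rest called at most 3, which points to a structure of the samples in which the inhibitor groups set the difference.

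Coding genes with a long genomic span were lower with inhibitor in WT cells. Of 586 genes of at least 300 kb, 65.4% were lower and 18.4% higher (median −0.82), against 37.6% and 40.6% of 2646 genes under 10 kb (median 0.06), whereas in ScURA cells 14.3% of the long genes were lower and 43.2% higher (median 0.24). Length and GC content were those of the longest annotated spliced transcript of each gene, which need not be the one expressed. That length as the cause is argued against by the partial Spearman correlation of the WT change with span. Given transcript length, GC content and expression, this was −0.171 over 13897 genes, against 0.085 for transcript length itself. GC content is argued against by a partial correlation of −0.128 given GC content and by values from −0.164 to −0.0991 within the 5 groups of genes by GC content, although the bound first set, all 5 below −0.1, was narrowly missed in 1 group. A candidate explanation, found and tested on the same data, is a lower output of long transcription units under inhibitor in WT cells but not in ScURA cells, where long genes were higher and whose partial correlation (0.0818) lay above that of WT cells by 0.248 to 0.259 with each library left out, but transcription was not measured, the correlations are weak and slower growth or RNA decay remain untested.

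Cytosolic ribosomal protein mRNAs fell in WT cells and rose in ScURA cells. In WT cells the median of 189 genes matched on expression, transcript length and GC content (−0.59) lay 0.79 above that of the ribosomal proteins (−1.38). With any 1 library left out it lay 0.759 to 0.818 above. Length and GC content were those of the longest annotated transcript (median 1842 bp for ribosomal proteins, 1879 bp for matched genes). That transcript need not be the one expressed, and median expression differed (9.54 against 9.07 log2 CPM). A class effect of abundant genes with like annotated transcripts is thus argued against as the whole cause. One of short expressed transcripts was not tested. Scaling is argued against by the median nearest to 0 over the scalings run, −1.03 with library totals alone, and by positive medians in ScURA cells with each. A candidate explanation is a joint change of mRNAs that begin with a 5' terminal oligopyrimidine tract, since 19 of 19 such mRNAs outside the list, chosen after ribosomal protein, EEF1A1 and NPM1 values were seen and without those genes, were lower in WT cells, at a median −0.774 from their matched genes, and 14 were higher and 0 lower in ScURA cells. Whether transcription or stability of these mRNAs changed stays open, and mRNA levels say nothing of their translation.

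Interferon-stimulated genes were higher in ScURA than WT cells under vehicle (median 0.78), fell with inhibitor in ScURA cells (−0.65) and rose in WT cells (1.04). An aberrant library is argued against for the difference under vehicle and the fall in ScURA cells. At least 16 of 29 members kept each of these 2 calls with any 1 library left out. Counting error in the ScURA vehicle libraries, which those calls share, is argued against by using 2 of these libraries in one comparison and the other 2 in the other: over the 6 ways, medians were 0.72 to 0.87 under vehicle and −0.77 to −0.529 with inhibitor. Between ScURA cells under inhibitor and WT cells under vehicle members went both ways (median −0.17, 16 of 29 below 0). A state common to all 4 ScURA vehicle libraries was not excluded, and a genotype effect stays open and untested, because expression of ScURA and any other difference between both cell populations, such as clonal history, cannot be separated with 1 population of each.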

How the results depend on the processing

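Scaling by library totals alone and list tests without mitochondrial genes were chosen after seeing the data; the other alternatives were set before the data were examined. Of 170 gene results named in the report, 155 kept their side of the threshold in every alternative run for them. None that was called in the main fit or in the alternative changed direction. Changes of sign in results called in neither fit were not counted. Of 26 alternatives, the fit to only the 2 groups compared was run for 134 of these results and that without mitochondrial genes for 163. The exceptions stand beside those genes. Scaling by library totals alone gave 4235 lower genes in WT cells instead of 6709 and moved the share of genes with the larger response in WT cells from 65.13% to 67.78%, as a scaling that shifts all genes of a library together would. For ScURA against WT cells under vehicle, the normalized counts deposited by the authors gave 231 higher and 116 lower genes in their smaller table, and leaving out 1 library gave 449 to 729 higher and 248 to 446 lower genes (the lowest without WT vehicle replicate 3). The cause of the first was not tested, and the other drops 1 of 16 libraries from the fit. Camera called 76 of 170 list tests, 2 with an estimated correlation and 133 with fry, which asks another question. Genes chosen on the WT response gave a share of 74.96% and a slope of 0.2097, and genes chosen on the ScURA response 49.13% and 0.6227, since each choice favours large responses in that genotype. The other counts of all called genes stayed within 1.5 times under every alternative run. The stricter filter, which tested 13558 genes, lowered counts at a 2-fold change: 2205 higher and 1545 lower in WT cells, 1157 and 652 in ScURA cells, 2003 more negative responses, and 1985 lower under inhibitor. Library totals alone gave 1493 lower in WT cells. Under vehicle the 2-fold counts of 62 and 52 became 140 and 101 with no filter, the lower one 22 with the stricter filter and 26 with limma-voom, and 34 with the authors' normalized counts. List calls numbered 73 with DESeq2 size factors, 61 with library totals alone, 75 without mitochondrial genes and 71 to 81 with 1 library left out. Counts with inhibitor against vehicle ranged, over libraries left out in turn, from 6896 to 7358 higher and 6546 to 6822 lower genes in WT cells and from 5285 to 5708 and 5270 to 5585 in ScURA cells.

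The labels number the replicates of each group alike, but nothing in them says that a number marks a shared culture or day. Deviations from the group means of libraries with the same number correlated at −0.128 to 0.094 over 24 pairs (mean −0.0013), and 3 of 16 libraries correlated best with one of their own number, so the numbers were not taken as pairs. With the replicate block the counts were 7025 higher and 6659 lower in WT cells, 5546 and 5450 in ScURA cells, 5630 and 5935 for the difference between responses, 632 and 368 for ScURA against WT cells under vehicle, and 6458 and 7303 under inhibitor, with 74 list calls (lost were the matrix list for the difference, adjusted p = 0.0501, NRF2 targets in ScURA cells, 0.0501, and fatty acid synthesis under inhibitor, 0.061, and gained were mitochondrial ribosomal proteins for the difference, 0.0457), a share of 65.13% and a slope of 0.3483. On counts simulated at these totals, with few genes changed, the test recovered 60%, 74% and 88% of 1.5-, 2- and 4-fold changes in WT cells. Depth was not varied in that simulation, so its part in the missed calls was not tested.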

Other observations

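Gene types, gene levels, MALAT1 and NEAT1 were looked at after their values were seen, as were MT-ND1 and MT-ND5 in WT cells and the difference for MT-ATP8. More lincRNAs and antisense genes were called higher than lower with inhibitor, by a wider margin in WT cells. Of 985 lincRNAs, 61.8% were higher and 14.3% lower in WT cells (median 1.29), against 26.8% and 16.6% in ScURA cells (median 0.24), and the response was more negative in ScURA cells for 43.5% and more positive for 12.6%. Antisense genes went the same way, with 52% of 1258 higher and 12.6% lower in WT cells (median 0.95) and 29.3% and 13% in ScURA cells (median 0.43). Coding genes were more even, with 36.6% of 13906 higher and 43% lower in WT cells and 33% and 35.5% in ScURA cells. The filter keeps a gene expressed in any 1 group, so scarce noncoding genes can enter through the WT inhibitor libraries alone. There noncoding RNAs took 2.15% of the counts, against 1.17% in WT vehicle libraries. Entry of this kind raises the share called higher in WT cells, and how many genes it concerns was not counted. The nuclear RNA MALAT1 went from 199 ± 22.9 to 852 ± 114 CPM in WT cells (2.10 ± 0.141, edgeR adjusted p = 2.41e-11) and from 201 ± 41.1 to 509 ± 106 CPM in ScURA cells (1.34 ± 0.14), a difference between responses of −0.76 ± 0.195 (adjusted p = 0.00191). NEAT1, which builds paraspeckles, rose by 1.95 ± 0.153 in WT and 1.58 ± 0.156 in ScURA cells (difference −0.37 ± 0.215, adjusted p = 0.135). Strand was not known here, so reads of antisense genes cannot be told from those of other genes where their exons overlap.

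Many genes near the floor of detection in vehicle libraries were detected with inhibitor in WT cells. Over all 60664 genes of the table, with no filter, 201 had a mean below 0.1 CPM in WT vehicle libraries and above 1 CPM with inhibitor, and 33 the reverse. In ScURA cells 19 and 7 did so. The difference between genotypes was not tested.

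Messenger RNAs of mitochondrial DNA changed unequally, and several responses differed between genotypes. In WT cells MT-ATP6 (−2.20 ± 0.0766), the adjoining MT-ATP8 (−2.00 ± 0.109) and MT-ND3 (−1.44 ± 0.0802) were lowest, while MT-ND1 went from 2769 ± 234 to 4010 ± 209 CPM (0.53 ± 0.0791) and MT-ND5 from 936 ± 85.5 to 1549 ± 86.9 CPM (0.73 ± 0.0675), each called by edgeR (n = 4 each). In ScURA cells MT-ND1 went from 2838 ± 109 to 1410 ± 224 CPM (−1.01 ± 0.0798), and MT-CYB from 2537 ± 129 to 846 ± 146 CPM (−1.58 ± 0.0833). The difference between responses was −1.54 ± 0.112 for MT-ND1 (adjusted p = 1.83e-10), −1.46 ± 0.116 for MT-CYB (adjusted p = 6.85e-10) and 1.44 ± 0.149 for MT-ATP8 (adjusted p = 3.63e-08). Poly(A) selection was used, and tails of mitochondrial mRNAs are short, so these values describe polyadenylated forms.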
